A study of Caenorhabditis elegans with 2 samples.

How the data were processed

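The samples are 2 biological replicates of a ChIP-seq experiment on whole L1 larvae carrying a GFP-tagged NHR-90 transgene, chromatin sheared by sonication and precipitated with an antibody against GFP, per the labels. Groups and replicate numbers were taken from the labels. Both replicates belong to 1 group, and the control library used upstream is not analysed here, so no comparison with a control or an untagged strain was made.

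The authors deposited peak lists in the narrowPeak layout for the builds ce10 and ce11. Per the file listings deposited with them, each replicate's list of candidate peaks and background was derived from its own alignments and a control, a pooled list from both replicates, and the optimal list by thresholding the irreproducible discovery rate on the others. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the authors' own, deposited without a stated scale, and signals were compared only as ranks or within a list. The q-value is deposited as −log10 and had a single value, 3.99, throughout the optimal list, so it was not used for ranking. The deposited column for p-values is filled with a placeholder and was not used. Files with read counts are not used here, so depth and counting error per sample are unknown. Peak calling sets which weak sites appear: a list of candidates that includes background reaches into noise by design.

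Coordinates are 1-based in ce11, whose chromosome lengths equal those of the reference WBcel235, and no coordinate was converted between builds. No ce11 peak reached past a chromosome end. The annotation was Ensembl release 115, with names of otherwise unnamed genes and tRNA products from RefSeq. A gene was called bound when an optimal summit lay from 1000 bp upstream to 200 bp downstream of the 5′ end of any of its transcripts. A summit can count for several genes, and annotated 5′ ends in this species are often trans-splice sites. The location of a summit was the coding exon, untranslated exon, intron, noncoding gene or intergenic base it fell on, in that order of priority. Away from 5′ ends means outside these windows for all genes except piRNAs.

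Overlap between replicates was 1 bp or more between equal numbers of strongest peaks, tested by 1000 rotations of the peaks round each chromosome. An optimal peak was matched to the strongest overlapping candidate of each replicate for the rank correlation. Density on X was tested with an exact binomial test. Gene lists (34, defined by symbol patterns) were tested with two-sided Fisher's exact tests, coding lists against protein-coding genes with a letters-number symbol and noncoding lists against all genes except piRNAs, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes that lie together share peaks, and peaks and genes are not biological replicates, so these p-values measure no spread between animals. The fixed microRNA pattern matched 8 genes, since the annotation writes most microRNA symbols with a species prefix. Motifs (17) and all six-mers were sought within 50 bp of each summit on either strand and in an equally wide window centred 300 bp away on a random side, tested by exact McNemar tests with the same adjustment. Intervals of shares are exact 95% binomial intervals.

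Named genes are those assigned to the 25 optimal peaks of highest signal (a peak without one is given by position and nearest gene), nhr-90 and unc-119, up to 4 bound members of highest signal of each list past the threshold, and up to 2 of each other list. A gene that this rule names is not reported here. Tests, lists, motifs, this rule and most alternatives were fixed before the data were examined. The alternatives were the 2066 strongest peaks, either replicate alone, the other build, other overlap and promoter rules, other backgrounds, narrower and wider motif windows and other control sequences. The nearest-5′-end alternative and the genes assigned to the strongest peaks leave out piRNAs, and promoter GC is that of each gene's first listed transcript. The nearest-5′-end alternative sets no limit of distance, so it also assigns summits outside the promoter windows, and coding and noncoding genes compete for each summit. Added after seeing the data were promoter shares of protein-coding genes or without piRNAs, X ratios by location, coding lists and motifs without peaks near small RNA genes, the microRNA species prefix, and lists stratified by promoter GC.

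The tests were checked on simulated data: with 60% of 4133 peaks shared between lists the overlap test gave 61.4%, and without sharing 3.19% against 3.25% in rotations. With 60% of proteasome genes, rounded down to whole genes, written directly into the bound set, their share was 57.6% by construction. Their list was called (adjusted Fisher's exact p = 1.2e-06), and 0 of the other 33 lists were. With no motif planted 0 of 17 motifs passed, and a motif planted in 9.32% of windows raised its share by 9.29%. The shares of genes and of windows restate what was planted, so they check the counting and not recovery from peaks. Simulated summits for the motif test lay at random positions, and simulated bound genes were drawn independently. These checks therefore do not cover summit windows that differ in GC from their controls, or neighbouring genes that share peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.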

Results

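Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where a tagged nuclear hormone receptor, NHR-90, sat on the genome of starvation-synchronised first-stage (L1) larvae of the nematode Caenorhabditis elegans, 6 h after synchronisation. The hermaphrodite strain, OP483, stably carries a transgene that makes NHR-90 fused to GFP and a FLAG tag in an unc-119 mutant background, and an antibody against GFP was used for the precipitation. The 2 samples, biological replicates 1 and 2, form 1 group of whole animals, so the comparisons are between the replicates, between regions of the genome and between groups of genes. A control library from which the authors derived their peaks is not analysed here. The peak lists hold no read counts, so the depth of each sample is unknown. The signal given for each peak is the authors' value and is used to rank and describe peaks within a list.

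The replicates shared most of their strong peaks. Among the 25 strongest optimal peaks, 4 were beside the ribosomal protein genes rpl-3, rpl-15, rpl-20 and rpl-35, 3 beside genes for SL2 trans-splicing RNAs and 8 on the X chromosome away from annotated 5′ ends. The peak with the highest signal in the authors' final list (1699.5) was at rpl-3, which encodes a protein of the large ribosomal subunit, and it ranked 1 in replicate 1 and 1 in replicate 2. Among the 4133 strongest peaks of each replicate, 79.7% of those of replicate 1 overlapped one of replicate 2 by 1 bp or more. With the peaks of replicate 2 moved round each chromosome the mean overlap was 2.86% and the highest of 1000 rotations 4.77% (one-sided permutation p by rotation = 0.001, the smallest 1000 rotations can give). Replicate 1 has 27854 candidate peaks in ce11 and replicate 2 has 26708, lists that by their label include background. The authors' final list (called optimal here, thresholded by the irreproducible discovery rate) holds 4133 peaks with a median width of 400 bp, which cover 1403 kb or 1.40% of the genome. They are the 4133 peaks of highest signal among the 30000 candidates called on the pooled replicates. Of the optimal peaks, 99.7% overlapped a candidate peak in both replicates, and 78.7% overlapped one of the 4133 strongest in both. Across the 4121 optimal peaks matched in both replicates, signal was correlated with a Spearman's rho of 0.799 (permutation p = 1e-05, the smallest 100000 permutations can give). That value is across peaks, which are not independent replicates. The optimal list was itself made from both replicates and thresholded on their reproducibility, so these shares and this correlation are not independent evidence of it.

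**Figure D1:**
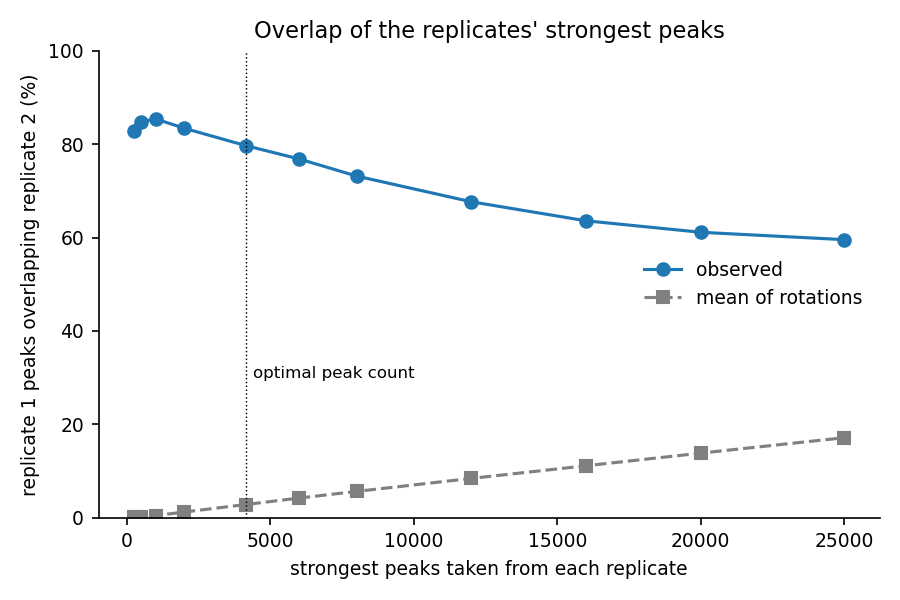
Percent of the strongest peaks of replicate 1 that overlap the equally many strongest of replicate 2 by 1 bp or more (y axis) against the number taken from each (x axis); squares are means of rotations and the dotted line marks the optimal peak count. Overlap is 85.4% for the strongest 1000 peaks, 79.7% at 4133 and 59.6% at 25000, each above its rotations.

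The 25 optimal peaks of highest signal ranked 32 or better in each replicate, with 22 of them among the strongest 25 of replicate 1 and 21 among those of replicate 2. In 15 of the 25 the summit lay from 1000 bp upstream to 200 bp downstream of a transcript 5′ end of a gene other than a piRNA, the rule used for calling a gene bound. The intergenic peak at rpl-3 spans 3867380 to 3867755 on chromosome III (ce11), with its summit 283 bp from the nearest 5′ end. Other ribosomal protein genes followed, at rpl-15 (IV, 654715 to 655084, signal 1298.6, also beside K11H12.8 and the snoRNA genes K11H12.12 and K11H12.13), rpl-20 (IV, 4749905 to 4750245, 1247.7, shared with Y17G9B.5) and rpl-35 (III, 7854540 to 7854845, 1242.3). Genes for SL2 RNAs, the spliced leaders added to downstream genes of operons, had 3 of these peaks: sls-2.4 (I, 4171943 to 4172539, signal 1446.7, beside R12E2.18 and egg-5), sls-2.1 (II, 5844606 to 5845183, 1173.4, beside H41C03.3) and sls-2.2 (II, 5543398 to 5543947, 1006.0, beside C17C3.22 and C17C3.23). The remaining gene-bound peaks on autosomes were at cdc-48.1 with the snoRNA gene C06A1.9, at tasp-1 with K01G5.10, at cmtr-1 with the snoRNA gene Y53F4B.47, at sec-61.G with F32D8.13, and at iff-2 with F54C9.14 and the snoRNA gene F54C9.12. On X they were at puf-9 with W06B11.7 and W06B11.9, at the noncoding RNA gene C18A11.13 and at nspc-17.

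In 10 of the 25 strongest peaks the summit was in no such window, and 8 of these were on X. The strongest of them (X, 9465600 to 9466126, signal 1266.4) was intergenic, 1853 bp from the 5′ end of ZK899.10. A second (X, 6296272 to 6296883, 1205.0) lay in an intron of mom-1, 3373 bp from the 5′ end of cest-16, and another (X, 5429344 to 5429794, 980.4) in a coding exon of pks-1, 9994 bp from the 5′ end of C41A3.6. Intergenic ones on X were at 13700591 to 13701095 (nearest gene K02D3.5, 3077 bp), 11093882 to 11094445 (the tRNA gene W02H3.t1, 1473 bp) and 806493 to 806876 (gtr-1, 3904 bp). The others were at 4209011 to 4209483 (F20B6.9, 1808 bp) and 12362903 to 12363400 (F19H6.5, 1715 bp). The autosomal pair was an intergenic peak on V (14055047 to 14055415, 1027.9), 1522 bp from the 5′ end of an unnamed pseudogene, and one in an intron of epg-9 on IV (2602008 to 2602364, 994.9), 1031 bp from a 5′ end of that gene.

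The X chromosome carried more optimal peaks for its length than the autosomes. It held 877 peaks, or 49.5 per Mb, against 32.1 per Mb on V and 49.04 per Mb on III, the lowest and highest of the autosomes. The X to autosome ratio of density was 1.25 (95% interval 1.16 to 1.35; two-sided exact binomial p = 5.3e-09, peaks taken as independent). Peaks away from annotated 5′ ends were the more concentrated on X, at a ratio of 1.56 (1.36 to 1.79), while peaks in promoter windows had 1.15 (1.05 to 1.26). Both ratios use full chromosome lengths, so differences in the amount of promoter and other sequence were not accounted for. Chromosome III had more promoter peaks per Mb (35.2) than X (33.5). X held 44% of the strongest 25 peaks, 22% of the strongest 100 and 17.4% of the strongest 1000, beside its 17.7% of the genome.

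**Figure D2:**
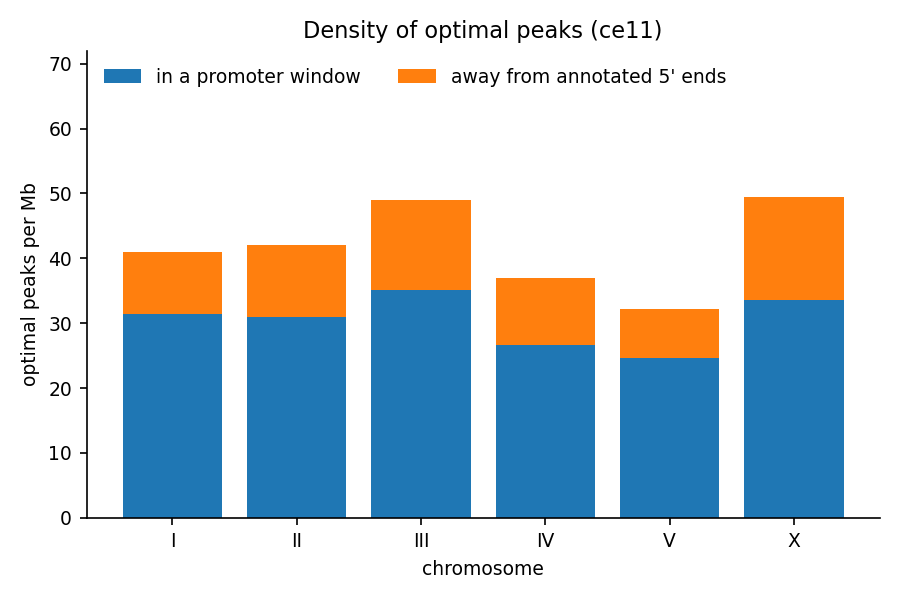
Optimal peaks per Mb (y axis) on each chromosome (x axis), split into summits in a promoter window of a gene other than a piRNA and summits away from them. X has 33.5 per Mb of the first kind and 15.97 of the second, chromosome III has 35.2 and 13.9, and chromosome V has 24.6 and 7.50.

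Optimal peaks lay mainly in intergenic DNA upstream of genes and seldom in coding exons. In all, 74.2% of summits were in the window from 1000 bp upstream to 200 bp downstream of an annotated transcript 5′ end, against a mean of 38.0% (SD 0.822) over rotations (two-sided permutation p by rotation = 0.002, the smallest they can give). Counting protein-coding genes alone the share was 58.3%, against 25.8% over rotations. Intergenic bases held 61.9% of summits (33.5% over rotations), noncoding genes 6.48% (3.75%), introns 22.6% (33.3%) and coding exons 3.51% (24.5%), each with an adjusted permutation p of 0.0025 by rotation. Untranslated exons held 5.54% of summits, against 4.93% over rotations (adjusted permutation p by rotation = 0.0839). Under the window rule 2927 of 19973 protein-coding genes, 14.7%, were bound.

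**Figure D3:**
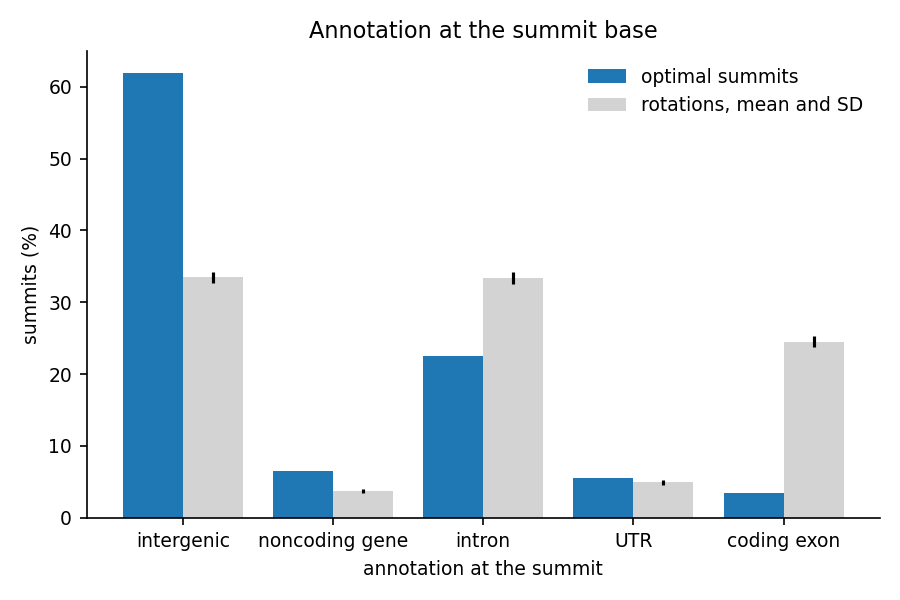
Percent of optimal summits (y axis) by the annotation at the summit base (x axis), beside the mean of 1000 rotations with their SD as error bars. Intergenic summits make up 61.9% against 33.5%, and coding-exon summits 3.51% against 24.5%.

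Genes for the synthesis, folding and breakdown of proteins and for respiration were bound more often than other genes. Of 82 cytosolic ribosomal protein genes 66 were bound, or 80.5% (exact 95% interval 70.3 to 88.4), against 17.9% of the other named coding genes. Proteasome subunits followed with 23 of 33, among them rpn-3 (signal 410.6), pas-5 (333.7), rpt-2 (289.4) and rpn-11 (287.6). Subunits of oxidative phosphorylation had 40 of 69, led by cox-5A (928.6), atp-1 (475.3), ndub-8 (396.7) and cox-6A (367.3). Translation factors and tRNA synthetases had 33 of 72, with iff-2 (944.2), eif-3.B (727.7), eif-3.C (688.3) and eef-1A.1 (556.7) the strongest. Heat shock proteins and co-chaperones had 23 of 56, with cdc-48.1 (1198.3), hsp-90 (919.2), hsp-60 (874.3) and hsp-3 (663.8). The pattern of that list adds cdc-48.1 by name. By two-sided Fisher's exact tests adjusted by Benjamini-Hochberg over 34 lists, the adjusted p-values were 2.6e-33 for ribosomal proteins, 1.2e-12 for oxidative phosphorylation, 6.4e-10 for the proteasome, 3.0e-07 for translation and 0.000233 for heat shock proteins. The last call was lost when each summit was given to the nearest 5′ end alone, at any distance (odds ratio 1.88, adjusted Fisher's exact p = 0.103). The odds ratios of the others fell, from 18.9 to 4.05 for ribosomal proteins, 10.3 to 4.18 for the proteasome, 6.22 to 2.66 for oxidative phosphorylation and 3.80 to 2.50 for translation. The proteasome's was 6.10 without replicate 2 and 3.65 among the 2066 strongest peaks.

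Small structural RNA genes were bound more often as well. Of 612 tRNA genes, transcribed by RNA polymerase III, 329 were bound (53.8%, interval 49.7 to 57.8), against 13.2% of all other genes except piRNAs (adjusted Fisher's exact p = 8.4e-120). The strongest tRNA gene peaks were at ZK994.t2 (tRNA-Lys, signal 524.1), C28G1.t1 (tRNA-Glu, 462.2), M01E5.t1 (tRNA-Lys, 436.5) and F47G6.t1 (tRNA-Arg, 429.7). For 291 tRNA genes an optimal summit lay within 100 bp of the gene itself. Genes for snoRNAs, which guide modification of ribosomal RNA, had 136 of 346 bound (adjusted Fisher's exact p = 1.5e-30), and those annotated as snRNA 39 of 129 (adjusted p = 8.2e-06). The strongest of the latter were sls-2.4, sls-2.1, sls-2.2 and sup-6 (848.9). Genes annotated as snRNA thus include SL2 RNA genes, of which 15 of 18 were bound, and the other snRNA genes were not tested apart. A neighbouring coding gene shared many of these peaks: 52.8% of the strongest snRNA gene peaks, 48.4% of those at snoRNA genes and 24.7% of those at tRNA genes were also in a coding promoter window. None of 20 rRNA genes was bound (adjusted Fisher's exact p = 0.199), and whether reads could be placed uniquely there was not examined. Of 8 genes matching the fixed microRNA pattern 2 were bound, mir-1831 (380.0) and mir-2214 (120.5; odds ratio 2.04, adjusted Fisher's exact p = 0.505). With the species prefix of most microRNA symbols allowed, the odds ratio was 1.18 (adjusted Fisher's exact p = 0.524), and for the 8 genes it was 3.75 without replicate 1 (0.162).

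Chemosensory receptors, F-box and BTB-MATH genes, C-type lectins, cuticle collagens, homeobox genes and pharynx markers were bound less often than other genes. Chemosensory receptors, which neurons use to detect odours, had 21 of 1365 members bound (1.54%, interval 0.955 to 2.34; adjusted Fisher's exact p = 5.2e-95), among them srh-16 (459.2), srh-2 (424.2) and sri-5 (372.0). F-box and BTB-MATH genes had 18 of 395 (adjusted Fisher's exact p = 1.1e-15), with fbxb-58 (634.2), fbxb-85 (574.4), fbxa-83 (471.9) and fbxa-90 (436.0). C-type lectins, lysozymes and antimicrobial peptides, genes of innate immunity, had 16 of 348 (adjusted Fisher's exact p = 8.6e-14), with clec-126 (326.9), clec-57 (262.0), fipr-17 (216.8) and clec-53 (145.3). Cuticle collagens had 16 of 176 (adjusted Fisher's exact p = 0.00222), with col-63 (402.3), col-71 (314.2), col-38 (257.3) and col-166 (205.1). The homeobox list had 7 of 88 (adjusted Fisher's exact p = 0.0218), with ceh-38 (314.6), lim-8 (169.6), ceh-20 (111.7) and ceh-39 (87.6). Its members were matched by symbol alone, and whether lim-8 encodes a homeodomain was not checked. Pharynx markers had 1 of 35, peb-1 (161.9; adjusted Fisher's exact p = 0.0342). The collagen, homeobox and pharynx calls were lost against all protein-coding genes as background (adjusted Fisher's exact p = 0.0930, 0.188 and 0.111). The homeobox call was lost also without replicate 2 (0.0626) and by the nearest 5′ end (0.121), and the pharynx call without replicate 2 (0.107) and in 4 further settings.

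Nuclear hormone receptor genes, the family of NHR-90 itself, were bound about as often as other genes: 47 of 274 (17.2%, interval 12.9 to 22.1) against 18.4%, with nhr-68 (563.2) and nhr-47 (408.9) the strongest (adjusted Fisher's exact p = 0.748). With each summit given to the nearest 5′ end alone, at any distance, they passed the threshold, at an odds ratio of 1.46 (adjusted Fisher's exact p = 0.0396). That rule also assigns the 27.2% of summits away from annotated 5′ ends. Genes of fat synthesis (5 of 27; elo-1 and fat-3) and of fat breakdown and lipid handling (27 of 121; ech-5 and cpt-2) did not pass the test, with adjusted Fisher's exact p of 1 and 0.488, and by the nearest 5′ end the second list passed as bound more often (0.0260). The odds ratio of fat synthesis was 1.01, but 0.556 without replicate 2 and 2.00 with a window of 2000 bp upstream, neither past the threshold. Detoxification genes did not pass it either: cytochrome P450 enzymes 9 of 75 (cyp-13A2 and cyp-43A1; adjusted Fisher's exact p = 0.319), UDP-glucuronosyltransferases 10 of 67 (ugt-20 and ugt-50; 0.721), glutathione S-transferases 7 of 49 (gst-27 and gst-20; 0.748) and ABC transporters 8 of 53 (haf-3 and abcf-2; 0.818). Members were matched by symbol alone, and whether abcf-2 acts in transport or detoxification was not checked. Among the 2066 strongest peaks the P450 and glucuronosyltransferase lists were bound less often than other genes (adjusted Fisher's exact p = 0.0114 and 0.0196).

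Markers of most tissues did not stand apart. Bound were 6 of 30 intestine markers (act-5 and hrg-1; adjusted Fisher's exact p = 0.892), 4 of 29 hypodermis markers (vab-10 and col-10; 0.748), 3 of 30 body wall muscle markers (unc-112 and act-4; 0.531) and 7 of 42 neuron markers (unc-108 and snb-1; 1). Germline markers had 3 of 50 bound, led by puf-9 and mex-1 (adjusted Fisher's exact p = 0.0587). Members were matched by symbol alone, and whether puf-9 marks the germline was not checked. The list passed as bound less often with a window of 2000 bp upstream (Fisher's exact, 0.00716), without peaks near small RNA genes (0.0212) and over strata of promoter GC (Mantel-Haenszel, 0.0328). Vacuolar ATPase subunits had 8 of 21 (vha-12 and vha-8; 0.0873), and passed as bound more often with that window (0.000381), by the nearest 5′ end (0.00587) and against all protein-coding genes (0.0204). Core and linker histones had 20 of 80 (his-37 and his-67; 0.275) and passed against all protein-coding genes (0.0419). Insulin peptides and growth signalling genes had 14 of 65 (ins-39 and rheb-1; 0.721), bHLH genes 5 of 38 (hlh-11 and hlh-30; 0.721), peroxisome biogenesis genes 2 of 11 (prx-19 and prx-6; 1) and vitellogenins, yolk proteins made in adults, none of 6 (0.748). For peroxisome biogenesis the odds ratio was 0.986, but 1.69 without replicate 1 and 0.445 without replicate 2, neither past the threshold. In total 8 lists were bound more often and 6 less often than other genes, and 16 of the 34 had an unadjusted p below the threshold.

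**Figure D4:**
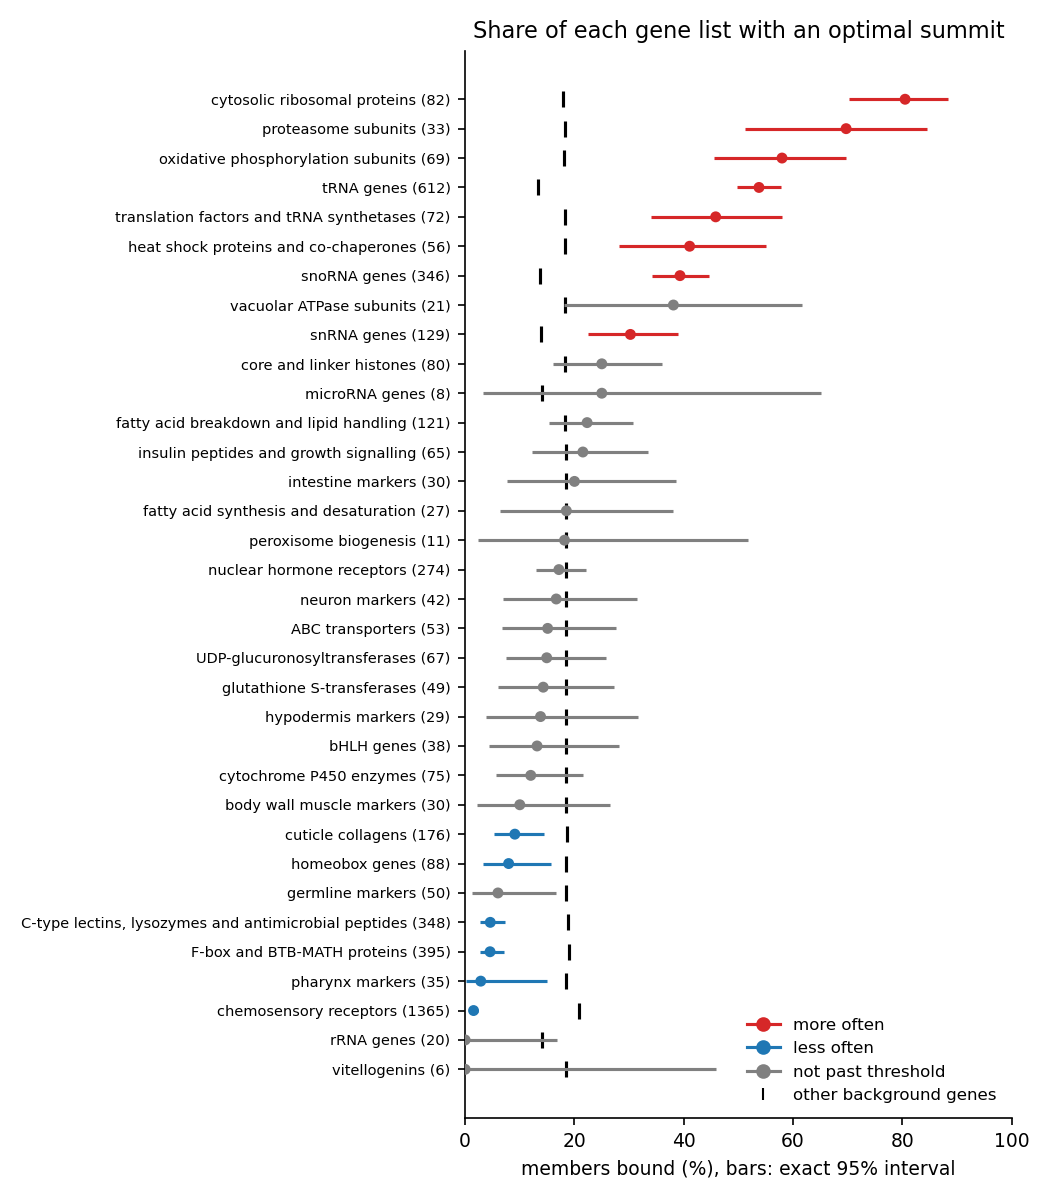
Percent of the members of each of the 34 lists with an optimal summit in a promoter window (x axis; list size in parentheses), with exact 95% intervals as bars and the share of the other background genes as a black tick. Ribosomal protein genes stand highest at 80.5%, and chemosensory receptors are at 1.54%.

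GAGA-type sequences and an E-box were more frequent at the summits, while of 3 sites typical of nuclear receptors AGGTCA alone passed as more frequent. The repeat GAGAGA was found within 50 bp of 23.2% of summits and in 5.98% of equally wide windows centred 300 bp away (ratio 3.89; adjusted exact McNemar p = 4.5e-113 over 17 motifs). The site GAGACGCAG of the zinc-finger protein EOR-1 was at 7.26% against 0.581%, a ratio of 12.5, and the E-box CACGTG at 8.13% against 1.72%. GGGCGG was at 6.00% against 1.96%, the forkhead site TGTTTGC at 5.78% against 1.89%, and the E2F-type site GCGCGAAA at 1.62% against 0.484%. Against dinucleotide-preserving shuffles these calls held, but the ratio fell to 2.30 for GAGAGA, from 4.73 to 3.11 for CACGTG and from 3.35 to 1.91 for GCGCGAAA. That of GAGACGCAG was 100 against shuffles, 24.3 among the 2066 strongest peaks and 21.4 against windows on the opposite side. These 3 ratios rest on only 3, 7 and 14 control windows with the site, so their size is imprecise. The core nuclear receptor site AGGTCA was at 4.21% of summits against 2.71% (ratio 1.55; adjusted exact p = 0.000348), a call lost among the 2066 strongest peaks (ratio 1.20, adjusted p = 0.397) and against dinucleotide-preserving shuffles (1.12, 0.386). Its variant AAGTCA (3.87% against 4.79%, adjusted exact p = 0.0632) and the HNF4-type site (0.387% against 0.484%, 0.730) did not pass. AAGTCA did pass, as rarer at summits, from either replicate alone (adjusted exact p = 0.00220 and 0.0183), among the 2066 strongest peaks (0.0489), in the narrower windows (0.0492) and against shuffles (5.5e-06).

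Of the other motifs, TTGCGCAA (ratio 4.00), the forkhead site GTAAACA (2.00) and TGATAA (1.27) were also more frequent at summits than in control windows, and the homeobox core TAATTA less frequent (0.417). The first was lost against the shuffles (adjusted exact p = 0.0853), and GTAAACA among the 2066 strongest peaks (0.610). The ratio of TTGCGCAA was 7.67 without replicate 1 (23 summit and 3 control windows) and 2.67 without replicate 2 (24 and 9). Its summit counts were thus nearly equal, and the ratios differ through few control windows. Among the 2066 strongest peaks TGATAA was instead rarer at summits, at a ratio of 0.760. Against shuffles its ratio was 2.25, and that of TAATTA was 1.04 (adjusted exact p = 0.866). AGATAA, CAGCTG, the AP-1 site and the heat shock element core did not pass, with adjusted exact p of 0.840, 0.161, 1 and 0.730. CAGCTG passed as more frequent from either replicate alone, in the narrower windows, against windows on the opposite side and against shuffles (ratios 1.64, 1.51, 2.35, 1.54 and 1.58). AGATAA passed as rarer among the 2066 strongest peaks (0.664) and as more frequent against shuffles (1.29), and the heat shock core against shuffles (4.60). Without a motif list, 1319 six-mers passed the threshold, 777 more frequent and 542 less frequent at summits. The leading ones were GAGAGA, AGAGAC (17.4% against 3.65%), AGAGAG and ACGCAG (13.7% against 2.30%). Summit windows averaged 44.7% GC (SD 8.14) and control windows 35.6% (SD 8.45), a difference that moves with these counts.

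**Figure D5:**
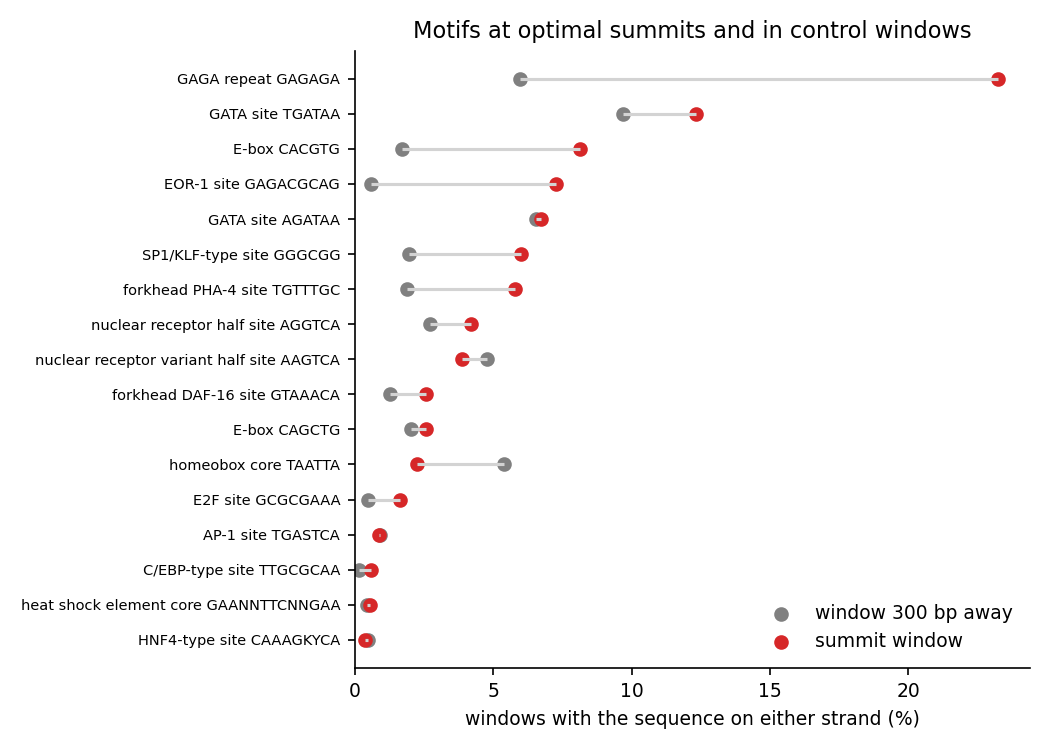
Percent of 4133 summit windows (red) and of control windows centred 300 bp away (grey) that hold each motif on either strand (x axis), for the 17 motifs. GAGAGA is at 23.2% against 5.98%, and TAATTA at 2.25% against 5.40%.

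The gene that supplied the tagged protein had no optimal peak nearby. Within 20 kb of nhr-90 (V, 610512 to 612513) there was no optimal peak, 1 candidate in replicate 1, ranked 10641, and none in replicate 2. The pooled candidates had none there, as few as in 1.90% of random 40-kb windows. Random windows of 40 kb held a median of 1 optimal peak, and 29.6% of them held none. Within 20 kb of unc-119 (III, 10902641 to 10908935), the neuronal gene mutated in the strain, there was 1 optimal peak (10895816 to 10896215, signal 71.0), ranked 4013, with 11 candidates in replicate 1 and 8 in replicate 2. Of the random windows, 70.4% held at least 1 optimal peak.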

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

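Candidate peaks just below the authors' threshold, which the comparisons in the report do not use, were chosen for a look after the data were seen. Of the 4133 pooled candidates ranked 4134 to 8266, 44.8% overlapped 1 of the 8266 strongest peaks in each replicate. The mean over 1000 rotations was 4.07% and the highest 5.83%. The pooled candidates were called on the reads of these same replicates, so an overlap above rotated positions was built in, and the share is given as a description, not as a test of agreement. In promoter windows of genes except piRNAs lay 58.1% of their summits, against 34.8% over rotations and 72.8% of optimal summits. No explanation was tested.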

How the results depend on the processing

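Alternatives added after seeing the data are named as such in the methods. Of the alternative values of the main results, 55 kept their direction and side of the threshold, or stayed within 1.5 times for a count. The other 4 follow from the settings: keeping only the stronger peaks leaves 2066 peaks and 1716 bound genes by construction, and windows of 50 kb either side held 1 optimal peak at nhr-90 and 2 at unc-119. The overlap share ranged from 58.2% (all candidates) to 83.4% (the 2066 strongest of each). With either replicate left out, the X ratio ranged from 1.20 to 1.23, the promoter share from 73.1% to 74.2%, bound genes from 2859 to 2943, lists past the threshold from 12 to 14, and six-mers from 1271 to 1292.

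Among the 14 called lists 140 alternative values kept their call, and 11 lost it with direction unchanged: 6 for pharynx markers, 3 for homeobox genes, 1 for collagens and 1 for heat shock proteins. For the called motifs 82 kept it and 4 lost it. TGATAA turned to a ratio of 0.760 among the 2066 strongest peaks, and TAATTA to 1.04 against shuffles that keep each window's composition. The causes were not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so its limits could not be set.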

Other observations

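The SL RNA genes split by type. Of 18 annotated SL2 RNA genes (sls-2), 15 were bound, while none of the 12 annotated SL1 RNA genes (sls-1) was. This pair was chosen after the strongest peaks were seen, and the difference was not tested. Whether reads could be placed uniquely at either set of genes was not examined, so a lack of peaks need not mean a lack of binding. Among tRNA genes the share bound was lowest for tRNA-Met (6 of 20) and highest for tRNA-Cys (84.6%, 11 of 13) among products with more than 1 gene, also untested.

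Chosen after the result was seen were the test of the whole X chromosome, the test of repeated against once-only tRNA genes and the masking of tRNA genes. The other tests were written before their own values were seen, but after first results on gene lists, motifs, the strongest peaks and peaks on X had been. No biological explanation given by the design was available, since there is 1 group.

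For peaks at tRNA genes, reads shared between copies were weighed with the 140 tRNA genes whose sequence occurs once in the genome. Of these 32.1% were bound (exact interval 24.5 to 40.6), above the 13.2% of other genes, the outcome set beforehand as arguing against shared reads. A sequence that occurs once can still have near-identical copies, and a summit in the window can belong to a neighbouring gene. Near-identical copies are therefore not excluded. The 472 repeated tRNA genes were bound in 60.2% of cases (odds ratio 3.19 against once-only ones, Fisher's exact p = 5.2e-09). Whether shared reads or a difference in activity brings that excess cannot be told apart without mappability or expression. Promoter GC is argued against as the whole source, as the odds ratio over 10 strata of it was 6.39 (5.43 to 7.53) beside 7.61 without strata. GC at the summit or in the tRNA gene itself was not stratified. General recovery of open or heavily transcribed chromatin stays open: AGGTCA was 2.57 times as frequent at these summits as in control windows (exact McNemar p = 0.0347), which met the bound set before that value was seen to argue against it, but 12 of the 18 matching windows had it only inside the tRNA genes themselves, and with these masked the count was 6 against 6. The test is therefore void, and an untagged strain would be needed.

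For ribosomal protein genes, promoter GC and neighbouring small RNA genes were tested as sources. Over 10 strata of promoter GC the odds ratio was 13.1 (7.69 to 22.2), beside 18.9 without strata. Without the 461 peaks within 500 bp of a tRNA, snRNA or snoRNA gene it was 12.4 (7.51 to 21.1), with 59 of 82 genes still bound. Both argue against these as the whole source. Recovery of heavily transcribed chromatin is open here too.

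X peaks away from annotated 5′ ends were weighed last, with the hypothesis that some are recruitment sites of the dosage compensation complex, which lowers expression from both X chromosomes of hermaphrodites. The core GCGCAGGG of the motif known at such sites was within 50 bp of 11 of 283 of these summits (3.89%) and of 0 of 843 autosomal ones (Fisher's exact p = 2.2e-07), and also of 6 of 594 promoter peaks on X and 1 of 2413 on autosomes. The 11 had a median signal of 938.6, beside 104.5 for the other X peaks away from 5′ ends, so the hypothesis may account for some strong peaks but leaves most of the 283 without the core. Near-identical copies are argued against by a median of 100% of 36-base stretches occurring once in the genome. A gain along the whole X cannot be told apart. The odds ratio of 1.36 between peaks away from 5′ ends and promoter peaks (Fisher's exact p = 0.000200) restates the pattern. It also takes no account of how much sequence of each kind X has. Promoter peaks were denser on X than on the pooled autosomes (ratio 1.15), but chromosome III had 35.2 per Mb beside 33.5 on X. The precipitation as such stays open without an untagged strain.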
